A study of Arabidopsis thaliana with 6 samples.

How the data were processed

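Single-cell RNA was measured by 10x Chromium 3' version 3 libraries in sorted protoplasts of Arabidopsis thaliana roots, 5 days after sowing by the labels. Protoplasts were kept when positive for the fluorescent reporter, negative for DAPI, which enters dead cells, and positive for DRAQ5, a DNA dye. Of the 6 samples of the series, 5 were analysed and the pAPL library was not analysed here. For each of the 5 libraries the authors deposited unfiltered counts, that is, UMIs (unique molecular identifiers) per gene and barcode, with no normalization, made with Cell Ranger 3.1.0 on the TAIR10 build per the labels. Each matrix lists 6794880 barcodes and 32836 features, of which 3 are the transgenes YFPer, 3xYFP and GFP. The annotation release is not stated. A TAIR10.1 annotation table supplied the gene symbols only: 32548 of the 32833 gene identifiers were in it and 10804 had a symbol. It pairs neither PINEAPPLE gene of the series title with an identifier, so these have no values here.

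Cells were called in each library as barcodes with at least 0.1 of the 99th percentile of UMIs among its 3000 deepest barcodes, at least 500 genes and under 10% of UMIs from 285 organelle genes. The UMI minimum so set ran from 1284 in SAPL to 11800 in MAKR5 root tip. Doublets were removed as the top share of Scrublet scores, 0.8% per 1000 called cells, which took 1 to 28 cells per library and left 4903 cells. Counts per cell were scaled to 10000 and logged (scanpy 1.11.5, Python 3.11.15), and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 27 clusters over the 5 libraries. Organelle genes were left out of the clustering, as were function list and reporter genes unless they were also cell type markers. The reporter gene bZIP6 is such a marker and helped to name the phloem pole pericycle-like clusters. A cluster took the name of a class, written with "-like", when at least 3 of its markers were at least 2-fold above the other clusters after adding 5 CPM (a gene's UMIs scaled to a sum of 1e+06), and stayed unnamed otherwise.

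Before the data were examined, 19 gene lists were fixed: 11 of cell type markers and 8 of functions, namely cell cycle, sugar transport and sucrose cleavage, amino acid transport, PEAR DOF factors, auxin transport, cytokinin, photosynthesis, and stress and wounding. A list of 5 reporter genes was fixed with them. All 205 entries matched a gene identifier in the files and 0 were moved to another identifier. The named genes follow a rule fixed at the same time. By stage, they are the 10 genes higher and the 10 lower with the greatest fold change among genes past the threshold whose libraries separate and whose higher stage reaches 10 CPM. Per list, up to 4 members past the threshold are named, or the 2 with the highest CPM where none passed. For the MAKR5 libraries, they are the 10 highest and 10 lowest ratios at 100 or more UMIs and the 2 members per list with the greatest ratio. Between classes, they are up to 10 function genes per direction. Reporter genes are always named.

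UMIs were summed over the called cells of each library. The labelled stages, 3 libraries against 2, were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after filterByExpr and TMM scaling, with Benjamini-Hochberg (BH) adjustment at 0.05 over 18601 genes. The 19 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with BH over lists, with camera at an estimated correlation, and with fry. Each library is a different reporter line or dissection, so the spread within a stage includes those differences, with 3 residual degrees of freedom. The MAKR5 root tip and whole root libraries, 1 each, were compared without a test, as log2 ratios of CPM with 95% intervals for counting error and against 10000 random lists matched on expression. Shares of cells have exact Clopper-Pearson 95% intervals, and CPM values have exact Poisson 95% intervals. Where a count is 0, the limit given is 3 counts of the total, except that transgene CPM of root cap-like, epidermis-like and endodermis-like cells has the exact Poisson upper bound. All of these cover counting error only. Values after ± are approximate SEs: the absolute log2 fold change of edgeR divided by the square root of its F statistic.

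Function genes were to be compared between classes with library as a block, over sums per library and class of at least 30 cells. The planned classes were sieve element, companion cell, phloem pole pericycle and procambium. That model could not be fitted: no pair of these classes shared 2 libraries, and with a block no residual degrees of freedom remained. Pairs of other classes were not part of the plan. An edgeR quasi-likelihood fit without the block was used instead, on 3 sums of sieve element-like cells and 2 of phloem pole pericycle-like cells, with BH over the 73 function genes tested. The DESeq2 alternative was run without the block for the same reason.

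The stage and class fits were tested on simulated data with the same group sizes. At a dispersion of 0.5 the stage fit recovered 32% of genes changed 16-fold and 0% of those changed 4-fold. At a dispersion of 0.1 it recovered 88% of genes changed 4-fold. The common dispersion of the stage fit was 0.313. Alternatives fixed beforehand were DESeq2 1.42.0, library totals in place of TMM, no filter on low counts, UMI minimums of 1000 and 3000, an organelle limit of 5%, no doublet removal, cells of a single class, Leiden resolutions of 0.5 and 2, at least 50 cells per sum, and leaving out each library. Alternatives chosen after seeing the data removed cells over 200000 UMIs, cells of classes outside the phloem pole, or the pericycle-like cluster led by stress genes.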

Results

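Transcriptomes of single cells were collected from the root phloem pole of Arabidopsis thaliana seedlings, using reporter lines in which the promoter of a phloem or pericycle gene drives a fluorescent protein. The series holds 6 samples with 1 library each, and 5 were analysed. Labels put 3 of these in the meristematic stage: MAKR5 root tip and MAKR5 whole root, which share the pMAKR5 line, and PEAR1del, from the pPEAR1(del) line. The S17 and SAPL libraries are labelled elongation zone shootward. MAKR5 root tip began from tips separated after 15 minutes in the protoplasting solution, and the others from a chopped part of the root that includes the tip. Total counts were 45549564 UMIs in MAKR5 root tip, 87906669 in MAKR5 whole root, 47550859 in S17, 6235052 in SAPL and 27335810 in PEAR1del. Called cells numbered 410, 1848, 1385, 726 and 534 in the same order. The median was 44263 UMIs per cell in MAKR5 root tip, 36707 in MAKR5 whole root, 17656 in S17, 2959 in SAPL and 25619 in PEAR1del. No sample has a replicate.

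Transgenes and reporter genes were compared between the libraries first. Each library held the transgene of its own line. The 3xYFP transgene reached 582 CPM (95% Poisson interval 572 to 592) in MAKR5 root tip and 159 CPM (156 to 162) in MAKR5 whole root. YFPer reached 300 CPM (282 to 319) in SAPL and 187 CPM (181 to 193) in PEAR1del, and GFP reached 35.9 CPM (33.9 to 38.0) in S17. MAKR5 (AT5G52870), a membrane-associated kinase regulator, stood at 797 CPM in root tip and 703 CPM in whole root, and at 11.7 to 33.5 CPM in the other libraries. The pMAKR5 line carries a MAKR5 fusion, so those counts can include the transgene. The pericycle transcription factor gene bZIP6 (AT2G22850), whose promoter is used in the S17 line, stood at 107 CPM in S17 and at 0.977 to 10.7 CPM elsewhere. SAPL (AT3G12730), a relative of the phloem identity gene APL, stood at 43.6 CPM in the SAPL library and at most 0.903 CPM elsewhere. PEAR1 (AT2G37590), a DOF transcription factor of early phloem, stood at 279 CPM in PEAR1del, 189 CPM in root tip, 45.7 CPM in SAPL, 36.5 CPM in whole root and 1.95 CPM in S17. APL (AT1G79430) stood at 182 CPM in root tip, 96.9 CPM in SAPL, 56.4 CPM in PEAR1del, 37.5 CPM in whole root and 5.50 CPM in S17. Free RNA, taken from barcodes under 100 UMIs, held several reporter genes at like or higher levels. These were SAPL at 57.9 CPM in the SAPL library, PEAR1 at 399 CPM in PEAR1del, bZIP6 at 96.9 CPM in S17, APL at 94.3 CPM in SAPL and MAKR5 at 44.1 CPM in PEAR1del. Sums over cells therefore do not show which cells expressed them. In other cases cells were above free RNA, which held PEAR1 at 109 CPM in root tip and 28.8 CPM in SAPL. It held APL at 21.8 CPM in whole root and 34.2 CPM in PEAR1del. MAKR5 in its own libraries was also above free RNA, which held it at 264 CPM in root tip and 403 CPM in whole root. So were the transgenes, for which free RNA held 3xYFP at 352 CPM in root tip and 110 CPM in whole root, YFPer at 73.7 CPM in SAPL and 65.1 CPM in PEAR1del, and GFP at 7.32 CPM in S17.

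**Figure D1:**
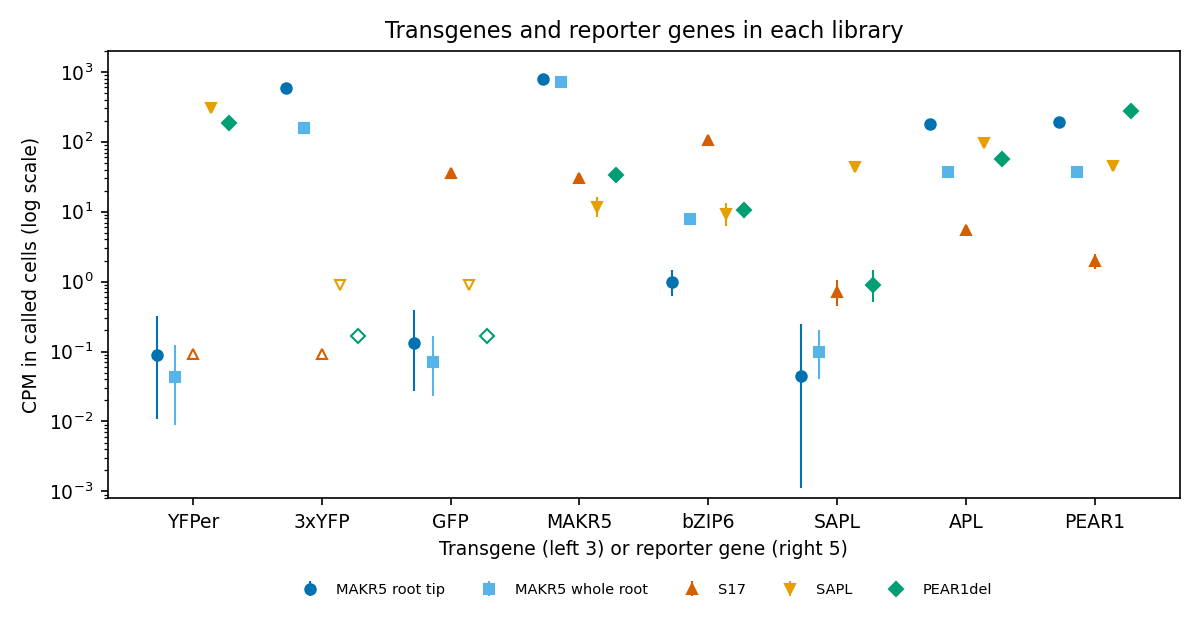
CPM of the 3 transgenes and 5 reporter genes (log axis) in called cells of the 5 libraries, with 95% Poisson intervals; open symbols mark the limit of 3 counts where no UMI was counted. Each own transgene lies between 35.9 and 582 CPM.

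Classes of cells differed between the libraries. Sieve element-like cells made up 27.8% of MAKR5 root tip (114 of 410, Clopper-Pearson 95% interval 23.5 to 32.4), 13.1% of MAKR5 whole root (242 of 1848, 11.6 to 14.7) and 9.18% of PEAR1del (49 of 534, 6.87 to 11.9). In S17 there were 3 such cells, and in SAPL 0 of 726, which allows a share of up to 0.413%. Phloem pole pericycle-like cells made up 57.0% of S17 (789 of 1385, 54.3 to 59.6) and 7.41% of MAKR5 whole root (137 of 1848, 6.26 to 8.70). They were 5.43% of PEAR1del and 3.99% of SAPL, 29 cells each, and the SAPL share fell to between 0.275% and 0.833% in the 6 alternatives of clustering and cell calling. In MAKR5 root tip they were 0 of 410, which allows up to 0.732%. Companion cell-like cells made up 51.4% of SAPL (373 of 726, 47.7 to 55.1) and at most 0.749% of any other library. Both of these leading shares moved with clustering and cell calling: the pericycle-like share of S17 was 20.5% at resolution 0.5, while the companion cell-like share of SAPL lay between 56.4% and 65.7% in 6 alternatives. Quiescent centre and stem cell-like cells made up 9.74% of PEAR1del (52 cells, 7.36 to 12.6) and numbered at most 4 in each other library. Xylem-like cells were 8.95% of SAPL, and root cap-like cells were 13.6% of SAPL and 8.43% of PEAR1del. No cluster met the rule for procambium or cortex. An unnamed cluster of 70 cells, all from SAPL, shared the leading genes FTIP1 and GBF6 with companion cell-like clusters. The companion cell-like share of 51.4% can therefore be too low. Unnamed clusters held 60% of root tip, 72% of whole root, 29.3% of S17, 16% of SAPL and 52.4% of PEAR1del cells. Of these, 4 clusters with listed cell cycle genes among their 10 leading genes held 27.3% of root tip, 33.5% of whole root and 29.6% of PEAR1del cells, against 0.650% of S17 and 2.48% of SAPL cells. A further unnamed cluster, led by histone genes such as HTA6 and HTA13 and singled out after its values were seen, would bring these shares to 41.7%, 47.3%, 43.6%, 1.01% and 2.89% in the same order.

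**Figure D2:**
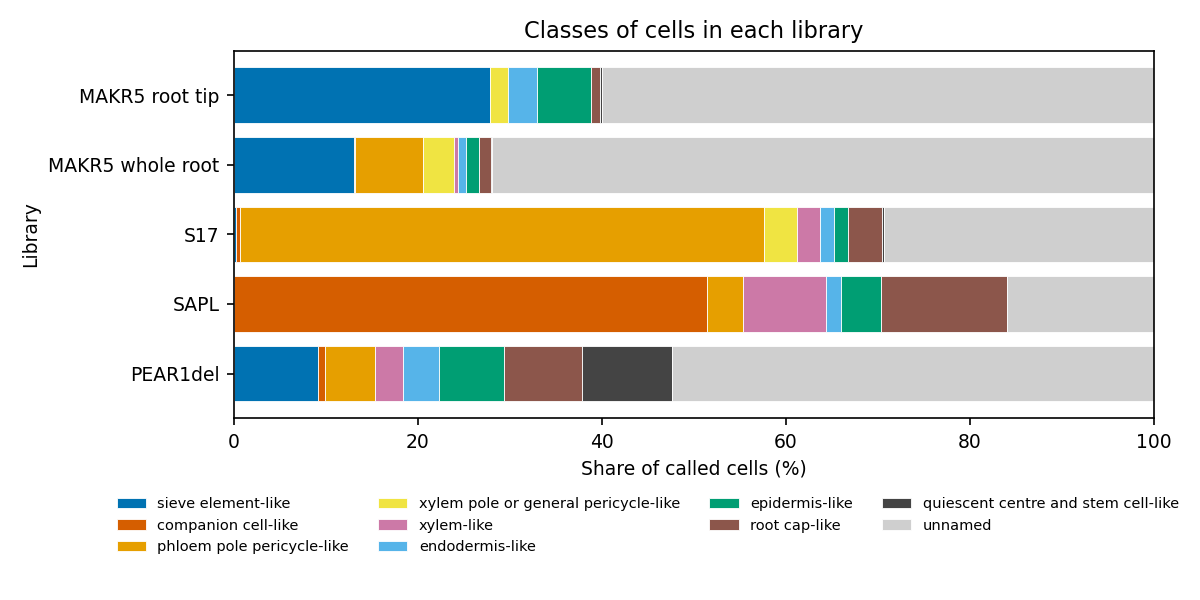
Share of called cells (%) in each class for the 5 libraries, as stacked bars that add to 100%. Companion cell-like cells fill 51.4% of SAPL and phloem pole pericycle-like cells 57.0% of S17.

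Within libraries, transgene levels were lower in root cap-like, epidermis-like and endodermis-like cells than in the class that each reporter was compared with. In PEAR1del, YFPer was 1309 CPM (1248 to 1374) in sieve element-like cells, 746 CPM in quiescent centre and stem cell-like cells and 0.493 CPM in root cap-like, epidermis-like and endodermis-like cells together. In SAPL, YFPer was 618 CPM (572 to 666) in companion cell-like cells and 20.4 CPM in those outer classes. GFP in S17 was 48.1 CPM in phloem pole pericycle-like cells, with 0 UMIs in the 92 outer cells, a 95% upper limit of 0.667 CPM. The 3xYFP transgene was 966 CPM in sieve element-like cells of root tip and 316 CPM in those of whole root, against 13.2 and 5.08 CPM in the outer classes. It was not highest there: in whole root it was 808 CPM in xylem pole or general pericycle-like and 430 CPM in phloem pole pericycle-like cells, and in root tip 1573 CPM in 8 xylem pole or general pericycle-like cells. The outer classes were 10.0% of root tip, 3.63% of whole root, 6.64% of S17, 19.7% of SAPL and 19.5% of PEAR1del cells.

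**Figure D3:**
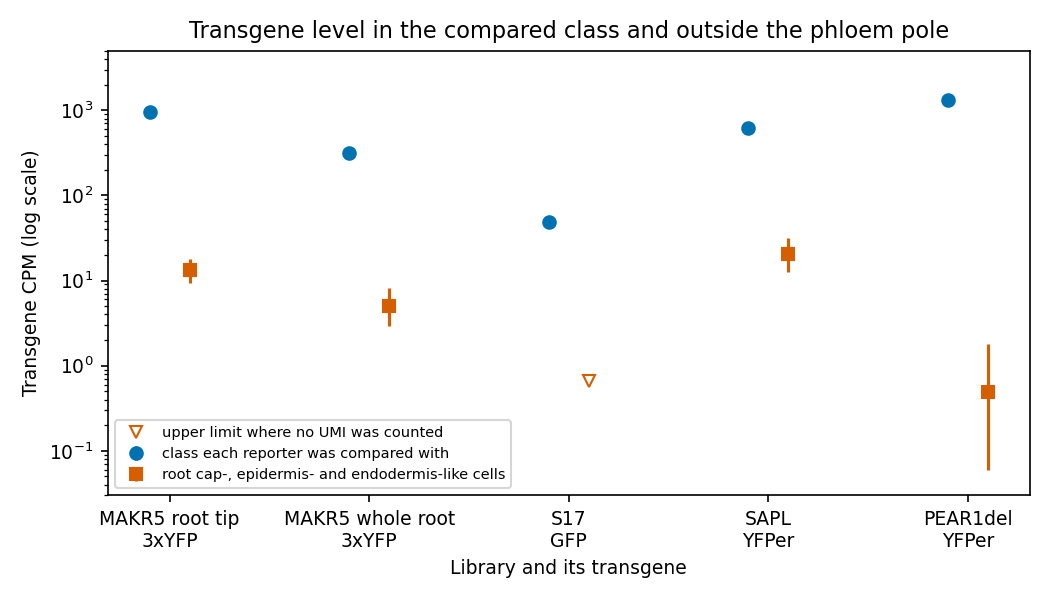
Transgene CPM (log axis) with 95% Poisson intervals in the class compared with each reporter (circles) and in root cap-like, epidermis-like and endodermis-like cells (squares; open triangle, upper limit at 0 UMIs). The circles lie between 48.1 and 1309 CPM and the squares at or under 20.4 CPM.

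Genes were next compared between the libraries labelled elongation zone shootward (S17 and SAPL) and those labelled meristematic. Genes of the cell cycle fell: 8 of 19 passed the threshold over all genes, all lower, and 19 of 19 adjusted over the list alone. The list passed camera (adjusted p = 3.83e-09), but not with an estimated correlation (adjusted p = 0.621). CYCB1;1 (AT4G37490), a mitotic cyclin, fell by 3.80 ± 0.61 (SE) on the log2 scale, from a mean of 25.7 to 2.18 CPM. Its mitotic companions AUR3 (AT2G45490), an Aurora kinase, and CDKB2;1 (AT1G76540), a cyclin-dependent kinase, had log2 fold changes of −3.25 ± 0.51 and −2.88 ± 0.48. MCM2 (AT1G44900), part of the replicative helicase, had −2.89 ± 0.41. Among root cap-like cells alone it had 0.52, with PEAR1del as the only meristematic library. BBM (AT5G17430), a stem cell transcription factor, was the 1 of 4 quiescent centre and stem cell markers that passed, at −4.61 ± 0.91, with 3 lower adjusted over the list alone. Of 11 sieve element markers, CVP2 (AT1G05470), a phosphoinositide phosphatase of protophloem, passed at −2.61 ± 0.49, and 6 were lower adjusted over the list alone. Alongside, root cap-like cells made up 3.61% of S17 and 13.6% of SAPL, against 0.976%, 1.35% and 8.43% of the meristematic libraries.

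Genes of sucrose and amino acid transport were among those higher in S17 and SAPL. SUC4 (AT1G09960), a sucrose transporter, rose by 2.32 ± 0.36 on the log2 scale, from 5.82 to 32.3 CPM, and was the 1 of 11 tested genes of sugar transport and sucrose cleavage past the threshold, with 3 higher adjusted over the list alone. AAP4 (AT5G63850), an amino acid permease, rose by 6.89 ± 1.22, from 0.0377 to 6.72 CPM, as the 1 of 6 amino acid transport genes past the threshold, with 3 adjusted over the list alone. Companion cell markers numbered 0 of 7 past the threshold and 4 higher adjusted over the list alone. The proton pump gene AHA3 stood at 172 CPM in SAPL and 3.34 CPM in S17, and FTIP1 at 205 and 3.52 CPM. Photosynthesis genes numbered 0 of 21 past the threshold and 0 adjusted over the list alone. HY5, a transcription factor of light responses, was at 118 CPM in S17 and 41.2 CPM in SAPL, against 32.3 to 54.2 CPM in the meristematic libraries, and RBCS1A, a Rubisco small subunit, was at 35.8 CPM in SAPL and at most 4.27 CPM in the others.

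Among the genes with the greatest changes, GBF6 (AT4G34590), a bZIP transcription factor, rose by 5.33 ± 0.74 on the log2 scale, from 9.90 to 426 CPM, with 700 CPM in SAPL and 153 CPM in S17. ATC (AT2G27550), a relative of the flowering repressor TFL1, rose by 5.58 ± 0.48, from 0.506 to 26.8 CPM. The beta-glucosidase gene BGLU34 (AT1G47600) rose by 6.93 ± 1.42. Its relative BGLU35 (AT1G51470) had 814 UMIs against 1, a pooled log2 ratio of 11.30 with a counting interval of 8.82 to 16.61. AT5G09765, AT5G41380, AT1G02705, AT5G63710, AT1G54575 and AT4G16980 rose by 5.34 to 7.13 on the log2 scale; AT5G09765 had 0.903 CPM in SAPL, its limit of 3 counts. At the other end, AT5G08391 had 4848 UMIs in the meristematic libraries and 0 in S17 and SAPL, at least 134-fold lower against a floor of 3 counts in each library. AT5G08391 was at 161 CPM in MAKR5 root tip, 10.3 CPM in MAKR5 whole root and 28.6 CPM in PEAR1del, and without root tip the limit is 39.0-fold. AT1G10657 had 1240 UMIs against 3, a pooled log2 ratio of −7.06 (−9.34 to −5.51). The glutaredoxin gene ROXY2 (AT5G14070) fell by 6.49 ± 0.79, from 42.3 to 0.668 CPM. WVD2 (AT5G28646), a microtubule-associated protein, fell by 6.46 ± 0.84, and the transcription factor gene NAC028 (AT1G65910) by 5.96 ± 1.1. AT3G44960, AT3G16070, AT5G14110, AT1G79420 and AT5G14920 had log2 fold changes from −6.73 to −5.99. Several of these genes led clusters found on 1 side only. GBF6 was a leading gene of clusters made up almost only of SAPL cells. AT5G08391 and AT5G14110 led a sieve element-like cluster with 49, 49 and 16 cells in MAKR5 root tip, MAKR5 whole root and PEAR1del, and 2 in S17. For such genes, stage cannot be told apart from the cells that were sorted.

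**Figure D4:**
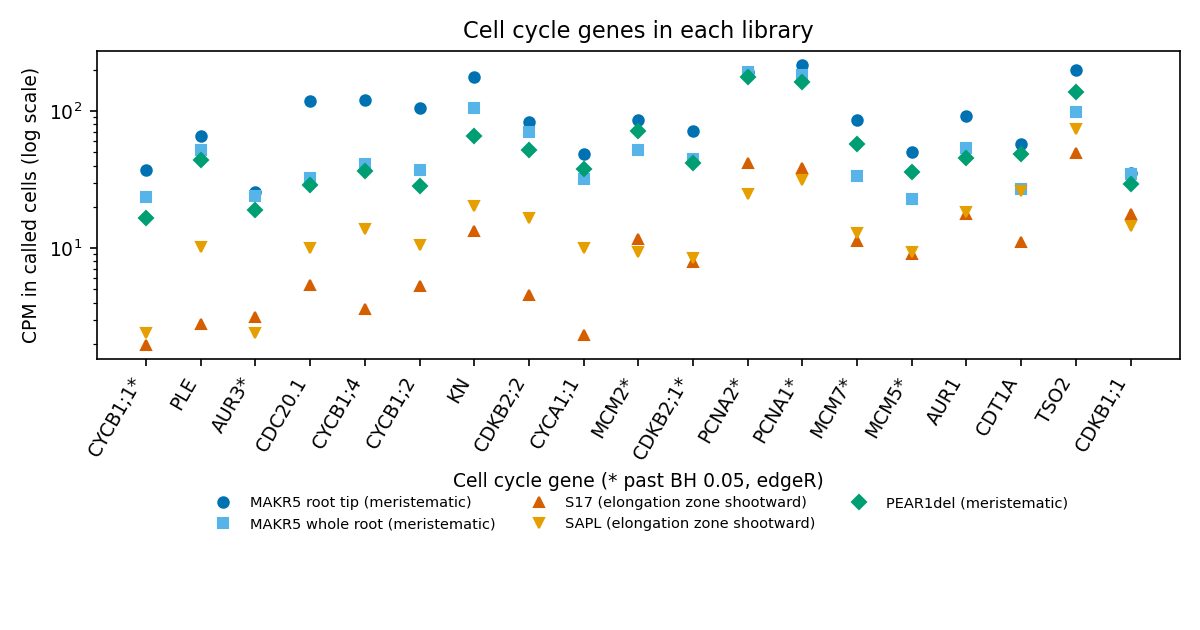
CPM (log axis) of the 19 cell cycle genes in the 5 libraries, 1 point per library; asterisks mark the 8 genes past the BH threshold of 0.05 in edgeR. In 19 of 19 genes S17 and SAPL lie below the 3 meristematic libraries.

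By edgeR with BH adjustment, 795 of 18601 genes passed, 258 higher and 537 lower in the elongation libraries. Adjusted p of the named genes past the threshold lay between 0.0491 and 0.05. DESeq2 with its own size factors gave 4496 genes, 2082 higher and 2414 lower. By camera at the preset correlation 6 lists passed: cell cycle lower (adjusted p = 3.83e-09), sugar transport and sucrose cleavage higher (0.00184), companion cell higher (0.0131), photosynthesis higher (0.0131), sieve element lower (0.0134), and quiescent centre and stem cell lower (0.0256). None held with an estimated correlation, where the adjusted p was 0.621 for cell cycle, sugar transport, companion cell and quiescent centre and 0.645 for photosynthesis and sieve element. With fry the lowest adjusted p was 0.0857, for cell cycle and for sugar transport. Marker lists follow which cells each sort delivered. Sieve element-like cells numbered 114, 242 and 49 in MAKR5 root tip, MAKR5 whole root and PEAR1del, and were nearly absent from S17 and SAPL. Companion cell-like cells were 373 of 726 in SAPL and rare elsewhere. Results for the sieve element and companion cell lists therefore largely restate the sort and do not test stage. The other lists had no member past the threshold, except AAP4 in amino acid transport, and camera adjusted p values of 0.0505 for endodermis (10 genes), 0.0570 for amino acid transport, 0.0761 for root cap (5), 0.0877 for stress and wounding (14), 0.0885 for PEAR DOF factors (6), 0.108 for xylem (8) and epidermis (9), 0.164 for phloem pole pericycle (6), 0.412 for cortex (4), 0.436 for cytokinin (11), 0.599 for auxin transport (8) and 0.969 for procambium (9) and for xylem pole or general pericycle (4). Adjusted over the list alone, 1 phloem pole pericycle gene was higher and 1 auxin transport gene lower. Median, mean and test differ in sign for auxin transport (median 0.63, mean −0.04, camera up), procambium (−0.05, −0.06, camera up) and xylem pole or general pericycle (0.61, 0.78, camera down).

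Reporter genes did not pass by stage: the log2 fold change was −4.96 ± 1.53 for MAKR5, 6.13 ± 1.75 for SAPL, 2.92 ± 1.17 for bZIP6, −2.79 ± 1.34 for PEAR1 and −0.91 ± 1.17 for APL. Of the lists without a member past the threshold, the 2 most abundant genes each gave the following log2 fold changes. In the phloem pole pericycle list these were 3.43 for the amino acid exporter UMAMIT18 and 3.27 for the callose synthase gene CALS8, and in xylem pole or general pericycle 1.98 for the phosphate exporter PHO1 and 0.05 for the zinc pump HMA4. Procambium had 0.37 for the cytokinin receptor WOL and −1.08 for the auxin response factor MP, and xylem had −2.22 for ACL5 and 1.70 for XCP2. Endodermis had 1.84 for ESB1 and 0.88 for CASP1, cortex 1.22 for C/VIF2 and −0.64 for JKD, epidermis 0.63 for WER and 2.40 for PRP3, and root cap 1.03 for BRN1 and 0.77 for SMB. The auxin carriers AUX1 and LAX3 had 1.40 and 1.86, the cytokinin response regulators ARR4 and ARR6 had 0.58 and 2.87, PEAR2 had −1.53, and the stress regulators ZAT12 and DREB2A had 1.87 and 0.86. The stage count became 0 without MAKR5 root tip, MAKR5 whole root, S17 or SAPL, with library totals in place of TMM and with a minimum of 3000 UMIs, and was 49 among root cap-like cells. Stage and reporter line cannot be told apart in this design, since each stage has its own lines.

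The MAKR5 libraries, of the same line, differ in dissection, and their comparison asks how the root tip differs from the longer root part. There is 1 library each, so no test was made. The ratios are over all called cells, and the mix of cells differed. Root tip had no phloem pole pericycle-like cell, against 137 of 1848 cells in whole root. Sieve element-like cells were 114 of 410 cells in root tip and 242 of 1848 in whole root. The ratios therefore cannot tell the mix of cells from changes within cells. By library totals the median gene was 0.60 log2 units higher in root tip, and TMM put the shift at 0.61, so ratios below are given relative to 0.61. Sieve element genes were higher in root tip: 8 of 11 were at least 1 log2 unit higher and 0 lower, with a median of 1.29. NAC086 (AT5G17260), a transcription factor of late sieve element maturation, was 5.01 log2 units higher (4.26 to 5.99), at 9.42 CPM in root tip and 0.185 CPM in whole root. NAC045 (AT3G03200), which acts with it, had 114 UMIs against 1, a ratio of 7.29 (5.36 to 13.18). PEAR1 was 1.76 higher (1.69 to 1.83), APL 1.66 (1.59 to 1.74) and DOF6, a further DOF factor, 1.58 (1.51 to 1.64); 3 of 6 PEAR DOF genes were at least 1 unit higher. Phloem pole pericycle genes were lower in 6 of 6 cases, with a median of −3.19. The sugar exporters SWEET12 and SWEET11 had ratios of −5.31 (−6.28 to −4.58) and, with 2 UMIs in root tip, −7.95 (−11.32 to −6.41), and bZIP6 had −3.59.

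Against 10000 random lists of like expression, the median of the sieve element list and of the PEAR DOF list lay at percentile 100, and that of the phloem pole pericycle list at percentile 0. Xylem pole or general pericycle genes (median −1.56, percentile 0.12), with PHO1 at −2.36 and SKOR at −2.45, and xylem genes (−5.97, percentile 0.28), with XCP1 at 1 UMI and XCP2 at 2 UMIs against 320 each, were low in root tip as well. Stress and wounding genes had a median of −1.11 (percentile 0.01), with WRKY40 at −2.89 and ZAT12 at −2.47. Within sieve element-like cells alone WRKY40 had 5 UMIs in root tip against 6 and ZAT12 had 23 against 16. Relative to the shift of 0.48 among those cells, these are ratios of −0.35 (−2.42 to 1.60) and 0.40 (−0.57 to 1.43), with no direction beyond counting error. Photosynthesis genes had a median of −0.72 (percentile 5.42), although LHCB1.3 had 2.30 and LHCB5 0.84. Cell cycle genes had a median of 0.13 (percentile 91.5), with CDC20.1 at 1.25 and CYCB1;4 at 0.95. Medians of the other lists were 0.01 for companion cell (AHA3 30.5 against 3.52 CPM, OPT3 0.14), −0.01 for procambium (TMO5 −1.89, WOL 0.56), 0.44 for endodermis (SCR 1.93, ESB1 0.44), 0.37 for epidermis (PRP3 0 UMIs against 121, RHD6 0.46), −0.03 for quiescent centre and stem cell (PLT2 0.83, BBM 0.29), 0.14 for sugar transport (SWEET17 −2.44, SUC3 0.97), 0.04 for auxin transport (PIN2 2.02) and −0.01 for cytokinin (CKX6 0.99, CKX5 0.54), at percentiles from 40.6 to 81.9. Cortex (JKD 0.91, C/VIF2 0.31), root cap (BRN1 1.07, BRN2 0.70) and amino acid transport (AT2G01170 0.61) had under 3 genes of sufficient depth for a median. PLT2 turned within sieve element-like cells, with 47 UMIs against 88 and a ratio of −1.01 (−1.56 to −0.49) relative to their shift. These cells differ in make-up: a late cluster holds 49 of the 114 in root tip and 49 of the 242 in whole root, so differences within the class can come from that mix.

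The 10 genes with the highest ratios in root tip include NAC045 and NAC086. The others were, in order, BGLU28 (129 UMIs against 0, at least 135-fold higher before the shift), FAR5 (128 against 2 UMIs), AT1G79480, GH9B6, EFE, NAC010, GSTF6 and AT3G10320, the last 6 at 4.51 to 5.22. EFE (AT1G05010), which makes ethylene, was at 20.5 and 0.511 CPM. At the low end, AT3G59370 had 2 UMIs against 16969, the peptide gene CLE5 (AT2G31083) had 5 against 11898, a ratio of −10.04, and AT4G39700 had 1 against 1525, with 1 against 0 within sieve element-like cells, too few for a direction there. AT3G59370 and CLE5 were among the leading genes of a pericycle-like cluster with no root tip cell and 16 whole root cells. AT4G39700 was among those of another, with no root tip cell and 78 whole root cells. PSK4, AT5G59080, AT1G52060, AT2G31110, UBC17, IAA19 and TPPJ had 0 UMIs in root tip and were at least 28.4-fold to 66.0-fold lower before the shift. MAKR5 itself had a ratio of −0.43 and SAPL had 1 UMI against 7. Of 15554 genes with at least 100 UMIs, 692 were at least 1 log2 unit higher and 2319 lower relative to the shift, against 4069 and 802 by library totals. Within sieve element-like cells the totals gave 1505 higher and 47 lower of 9710.

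Function genes were last compared between phloem pole pericycle-like cells (sums of S17 and MAKR5 whole root) and sieve element-like cells (sums of MAKR5 root tip, MAKR5 whole root and PEAR1del). All 19 cell cycle genes were lower in pericycle-like cells, among them the mitotic genes PLE at −6.23 ± 0.76 on the log2 scale, CYCB1;4 at −5.58 ± 0.81 and CDKB2;2 at −5.42 ± 0.66, and the replication licensing gene CDT1A at −5.33 ± 0.77. CYCB1;1 had 0 UMIs in pericycle-like cells and was at least 6.30-fold lower, and CDC20.1 had 1 UMI against 152. Both classes leave out 4 unnamed clusters led by cell cycle genes, with 620 of 1848 cells of MAKR5 whole root and 9 of 1385 of S17. A dividing pericycle cell in those clusters would not count as pericycle-like. A sieve element-like cluster shared the leading genes AT4G28310 and AT3G52630 with 1 of the 4. The clustering can therefore set part of this contrast. Of 6 PEAR DOF genes 5 were lower: PEAR1 at −9.38 ± 0.96 (813 to 1.15 CPM), DOF6 at −7.66 ± 0.56, HCA2 at −7.09 ± 0.49, PEAR2 at −5.62 ± 0.70 and TMO6 at −3.27 ± 0.46, while OBP2 had 0.05 ± 0.41. Photosynthesis genes were higher in 12 of 13 cases, and in 6 of 8 at Leiden resolution 0.5. GLK2 (AT5G44190), a regulator of chloroplast development, had 39.2 CPM in pericycle-like cells and 0 UMIs in sieve element-like cells, at least 35.7-fold higher. LHCA3, of photosystem I, was at least 12.5-fold higher, and PSBO1, of photosystem II, had 247 UMIs against 1, a pooled log2 ratio of 7.66 (5.17 to 12.97).

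Sugar transport and sucrose cleavage genes were higher in pericycle-like cells in 6 of 8 cases, with SWEET17 at least 20.4-fold and SWEET14 at least 3.01-fold higher, both at 0 UMIs in sieve element-like cells. SUC1 was at 28.1 against 0.166 CPM, and SUC4 had 2.01 ± 0.33. Of 6 cytokinin genes 3 were higher (5 at Leiden resolution 0.5): the response regulators ARR6, with 3539 UMIs against 2 and a pooled log2 ratio of 10.50 (8.64 to 13.54), and ARR5, at 5.78 ± 0.51, and the cytokinin synthesis gene IPT5, at least 8.39-fold higher. The degradation gene CKX6 was lower at −2.11 ± 0.71, a call that ended with DESeq2, with doublets kept, at Leiden resolution 0.5 and without either MAKR5 library. Of 6 auxin transport genes 2 were higher and 2 lower, with PIN3 at 1.71 ± 0.30, PIN7 at 1.57 ± 0.32 and LAX2 at −2.15 ± 0.38; without MAKR5 whole root 5 of 7 were higher. Of 2 amino acid transport genes AAP2 was higher. Without MAKR5 whole root 2 of 3 were higher, but without S17 and without the stress-led cluster described below no gene of this list passed. Stress and wounding genes were higher in 13 of 13 cases, with ZAT12 at 7.85 ± 0.62, ZAT10 at 7.64 ± 0.57 and WRKY40 at 9.10 ± 0.97. In MAKR5 whole root, 78 of the 137 pericycle-like cells lay in a cluster led by HSP18.2 and WRKY40; without that cluster 7 of 12 stress genes and 14 of 15 photosynthesis genes passed. Without MAKR5 whole root 8 of 13 stress genes were higher and 1 lower. Of the 13, 5 were lower in pericycle-like cells of S17 than in sieve element-like cells of PEAR1del: DREB2A, HSP17.6II, HSP17.6C, HSP101 and HSFA2 stood at 36.6, 8.84, 4.28, 26.0 and 17.1 CPM against 67.8, 30.4, 28.1, 75.6 and 35.9 CPM.

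**Figure D5:**
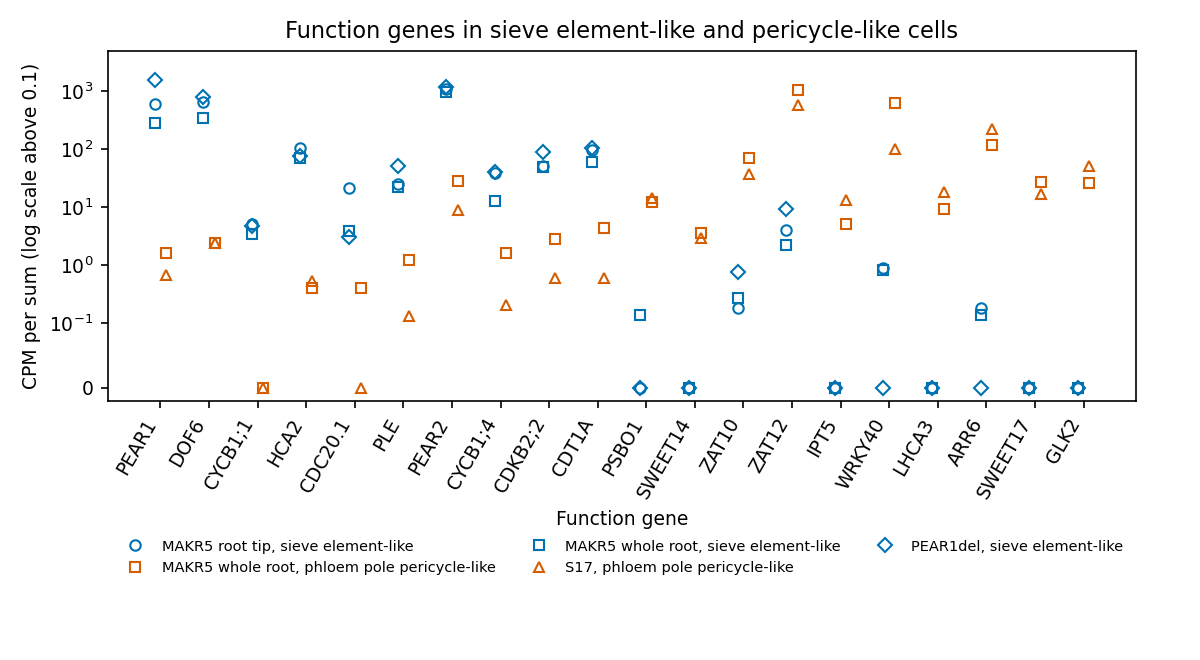
CPM (log axis above 0.1) of the 20 named function genes in 3 sums of sieve element-like cells (blue) and 2 sums of phloem pole pericycle-like cells (orange). PEAR1 averages 813 CPM in blue and 1.15 CPM in orange, and GLK2 0 and 39.2 CPM.

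In this edgeR comparison with BH adjustment over function genes, 64 of 73 genes passed, 37 of them higher in pericycle-like cells, and adjusted p of the named genes ran from 1.64e-06 to 0.00168. The share of all genes that differed was not counted, but it was large. HSP17.6C, at an unadjusted edgeR p of 0.0239, still had an adjusted p of 0.0405 over all genes. A count of genes past the threshold in a short list therefore does not single out its function. Counts adjusted over the list alone were the same as those above for each list. Within MAKR5 whole root, the 1 library with both classes, 64 of the 64 genes had the same direction. The fit has no library block, and that library gave a sum to each class. All sums of sieve element-like cells came from libraries labelled meristematic. Of the phloem pole pericycle-like cells in the fit, 789 came from S17, labelled elongation zone shootward, and 137 from MAKR5 whole root. MAKR5 root tip had no such cell, so within MAKR5 whole root the classes may also differ in position along the root. The contrast therefore cannot tell cell class from labelled stage or position.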

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

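Chosen only after their results were seen were the tests of GFP alone and of YFPer alone, both tests of misassigned reads by protein and the 3 tests of the cell cycle pattern; the other tests here were written beforehand. Transgene UMIs stood in libraries whose lines do not carry them, at more than the 3 counts that a count of 0 allows. MAKR5 root tip held 4 YFPer UMIs and 6 GFP UMIs. MAKR5 whole root held 19 YFPer UMIs and 10 GFP UMIs. PEAR1del held 22 UMIs of 3xYFP and 4 of GFP. SAPL held 3 GFP UMIs, at that limit, and their 3 barcodes are counted below. For comparison, MAKR5 whole root held 13608 UMIs of its own 3xYFP and PEAR1del 4167 of its own YFPer.

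For 3xYFP, 19 of the 22 barcodes in PEAR1del, 86.4% (exact 95% interval 65.1 to 97.1), also held 3xYFP in MAKR5 whole root, and 0 did so in MAKR5 root tip. For YFPer, 14 of the 22 barcodes, 63.6% (40.7 to 82.8), held it in a source library; all 14 were in MAKR5 whole root and matched PEAR1del, so both values are consistent with index swapping between those libraries. The GFP UMIs argue against swapping from S17, since 0% of 23 barcodes matched it (upper bound 14.8), and over GFP and YFPer together 31.1% (18.2 to 46.6) matched. Reads of a fluorescent protein assigned to another are argued against over all foreign barcodes, of which 28.4% (18.0 to 40.7) held the library's own transgene, and as the whole source of YFPer and 3xYFP, with 13.6% (5.17 to 27.4). Both shares lie above those among all barcodes, 0.170% and 0.150%. In MAKR5 root tip 3 of the 4 YFPer barcodes held its own 3xYFP and 0 held YFPer in a source library, so the source of those 4 stays open. For GFP alone that share was 56.5% (34.5 to 76.8), so misassigned reads may be the source of GFP; no biological explanation was tested.

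Cells of the root cap-like, epidermis-like and endodermis-like classes made up 3.63% to 19.7% of libraries sorted for phloem pole reporters. Transcription of the reporter in these cells is argued against: the ratio of their transgene CPM to that of the class compared with each reporter was above 0.5 in 0 of 5 libraries. It was under 0.2, upper bound included, in 5 of 5 libraries, with the highest ratio 0.0331 (0.0203 to 0.0510) in SAPL. These values are consistent with cells that were carried through the sort without expressing the reporter. Fluorescent protein that persisted or moved was not measured and stays open. These classes need not hold all cells without reporter transcripts. The 29 phloem pole pericycle-like cells of PEAR1del held 1 YFPer UMI, and the 29 of SAPL held 0. Of unnamed cells, 27.5% in PEAR1del held a UMI of the library's own transgene. That share was 51.5% in S17, 65.5% in SAPL, 94.5% in MAKR5 whole root and 97.6% in MAKR5 root tip.

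Cell cycle genes were lower in S17 and SAPL, with a median log2 fold change of −2.89. The lower depth of SAPL as the whole cause is argued against, since S17 alone was below all 3 meristematic libraries for 19 of 19 genes. Cells in clusters named as classes outside the phloem pole are argued against as the whole cause too: without them the median was −2.78, with 19 of 19 genes lower and 12 past the threshold of edgeR. Unnamed clusters were kept, among them the 4 led by cell cycle genes. In PEAR1del 27.5% of the 280 unnamed cells held a YFPer UMI, against 100% of the 49 sieve element-like cells. Unnamed cells from outside the phloem pole therefore stay open as a cause. The labelled stage itself stays open, because each stage has its own reporter lines. With the pMAKR5 line held fixed, the median ratio of root tip over whole root was 0.13 relative to the shift, and both of those libraries carry the meristematic label, so stage and reporter line cannot be told apart.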

How the results depend on the processing

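Removal of cells over 200000 UMIs, of cells outside the phloem pole and of the stress-led cluster was chosen after seeing the data; all other alternatives were planned. The stage count was 795 (258 higher, 537 lower). DESeq2 gave 4496 (2082 and 2414), no filter on low counts 1299 (333 and 966), removal of cells outside the phloem pole 4497 (2061 and 2436), and root cap-like cells alone 49 (39 and 10). With library totals, which moved the median log2 fold change from 0.05 to 0.18, it was 0 (0 higher, 0 lower; 5059 genes at an unadjusted p under 0.05), and with at least 3000 UMIs 0 (0 and 0; 5522). A minimum of 1000 UMIs gave 990, the 5% organelle limit 839, no doublet removal 867 and removal of cells over 200000 UMIs 1163. Leaving out each library in turn gave 0 to 522 genes, 0 to 208 higher and 0 to 314 lower. edgeR gave 0 without MAKR5 root tip, MAKR5 whole root, S17 or SAPL (3992, 4193, 4949 and 5633 genes at an unadjusted p under 0.05), where fewer libraries leave 2 residual degrees of freedom, and 522 without PEAR1del. Where S17 or SAPL is left out, the lone elongation library is assumed to vary like the others. Of the 795 genes, 795 passed in DESeq2, 779 without cells outside the phloem pole, 385 without PEAR1del and 12 among root cap-like cells alone. The cause of these differences was not tested.

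The 6 lists past camera became 0 with an estimated correlation and 0 with fry, and 6 to 9 when a library was left out. By camera, sieve element did not pass without MAKR5 root tip (adjusted p = 0.0624) or S17 (0.0801), nor photosynthesis without S17 (0.0689) or PEAR1del (0.0580). Lists that came to pass were amino acid transport without MAKR5 root tip or S17, stress without S17 or PEAR1del, and xylem without MAKR5 whole root. Without SAPL both pericycle lists and PEAR DOF factors came to pass, and without PEAR1del endodermis, epidermis and root cap. Of the fold changes of named genes by stage, 626 were the same in direction and side of the threshold, 188 kept direction but did not pass, and 17 came to pass. Those that reversed, besides MCM2 none past the threshold, were HMA4 at −0.015 and RBCS1A at −0.30 with no filter and with at least 3000 UMIs, in that order, and WER at −1.82 without cells outside the phloem pole. Among root cap-like cells they were MP 0.71, WER −0.44, BRN1 −0.24, MAKR5 3.48, MCM2 0.52, ZAT12 −0.47 and DREB2A −1.03. Leaving out a library turned 6 genes without S17, giving ranges over the 5 omissions of −2.09 to 5.78 for UMAMIT18, −2.69 to 0.87 for HMA4, −3.92 to 4.12 for PHO1, −0.16 to 0.66 for WOL, −4.25 to 0.013 for APL and −0.17 to 1.19 for HY5. Leaving out SAPL turned AHA3 (−2.12 to 4.23), RBCS1A (−0.31 to 9.92) and DREB2A (−0.72 to 2.08), and leaving out PEAR1del turned ACL5 (−3.25 to 0.51), JKD (−1.20 to 0.057) and HMA4, which MAKR5 root tip turned as well. The cause was not tested.

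For root tip against whole root, the 4871 genes at least 1 log2 unit apart became 3011 (692 higher, 2319 lower) with TMM, by the 0.61 that it removes, and 1552 (1505 and 47) among sieve element-like cells, where 9710 genes had the depth. There PLT2 was −0.53 (−1.08 to −0.0054; 47 UMIs against 88), against the other sign in all cells; the cause was not tested. AT4G39700 was 1.96 from 1 UMI against 0, WRKY40 0.13 (−1.94 to 2.09) from 5 against 6 and ZAT12 0.88 (−0.087 to 1.91) from 23 against 16, so their sign there is not settled. The shift among those cells was 0.48, and the late cluster is a larger part of them in root tip (49 of 114 cells) than in whole root (49 of 242). The counts with at least 1000 or 3000 UMIs, with doublets, or without cells over 200000 UMIs or outside the phloem pole lay between 4510 and 4971.

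A minimum of 1000 UMIs gave sieve element-like shares of 21.3% in MAKR5 root tip and 11.4% in MAKR5 whole root. The pericycle-like share of S17, 57.0%, became 20.5% and 52.8% at resolutions 0.5 and 2, 40.5% and 39.3% at 1000 and 3000 UMIs, 52.9% at the organelle limit of 5% and 45.1% with doublets. The companion cell-like share of SAPL, 51.4%, became 65.7%, 56.5%, 64.6%, 56.4%, 65.6% and 65.2% in the same order. Clusters that take another name move as a whole; the cause was not tested further. Function genes between classes numbered 57 to 69 past the threshold over all alternatives and 61 to 69 when a library was left out, with 196 of 196 fold changes the same in direction and side for the 20 genes of greatest change. Other genes changed: without MAKR5 whole root 8 stress genes were higher and 1 lower, and 5 auxin transport genes higher and 2 lower, and without S17 2 auxin transport genes were higher and 3 lower. At Leiden resolution 0.5 photosynthesis had 6 of 8 higher, sugar transport 4 of 7 and cytokinin 5 of 6. The only lower cytokinin gene, CKX6, lost its call in 5 alternatives and the only higher amino acid transport gene, AAP2, in 2. The cause was not tested. For the planned classes the library block, and DESeq2 with it, could not be fitted. Pairs of other classes were not part of the plan and were not fitted. SAPL, with 3324337 UMIs in cells, limits what is seen at low expression: 3 counts are 0.902 CPM there and 0.0426 CPM in MAKR5 whole root.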

Other observations

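The test of cell cycle genes in late sieve element-like cells was written beforehand. Companion cell-like cells of SAPL held transcripts of sucrose and amino acid handling genes: SUS1, a sucrose synthase, at 91.0 CPM, SUC4 at 73.0 CPM, the sucrose transporter SUC2 at 41.4 CPM, and the amino acid permeases AAP5, AAP2 and AAP4 at 61.3, 55.9 and 33.3 CPM. In pericycle-like cells of S17 these stood at 4.55, 34.2, 1.09, 4.62, 3.19 and 1.22 CPM in the same order. SUC2 is among the markers that named the companion cell-like clusters, so its difference was set by the naming. The auxin efflux carriers and importers were abundant in quiescent centre and stem cell-like cells of PEAR1del, with LAX2 at 1272 CPM, PIN4 at 1183 CPM, PIN3 at 681 CPM and PIN7 at 366 CPM, against 5.64, 59.5, 37.8 and 58.1 CPM in pericycle-like cells of S17. LAX3 was at 1194 and 1469 CPM in xylem-like cells of S17 and SAPL and at 5.78 CPM in pericycle-like cells of S17.

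Xylem pole or general pericycle-like cells of MAKR5 whole root (62 cells) had LHCB6 at 64.7 CPM, PSBP1 at 62.0 CPM and GLK2 at 39.5 CPM, genes of light capture, of photosystem II and of chloroplast development, against 23.4, 28.2 and 26.6 CPM in its phloem pole pericycle-like cells. The 3xYFP transgene was at 808 CPM (756 to 862) in these cells of MAKR5 whole root and at 1573 CPM (1403 to 1757) in the 8 such cells of MAKR5 root tip, against 316 and 966 CPM in sieve element-like cells. In S17, 406 cells of unnamed clusters held GFP at 42.7 CPM (38.8 to 46.9), next to 48.1 CPM in pericycle-like cells.

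Sieve element-like cells fell into 1 late cluster, with NAC045 and NAC086 among its markers, and 2 early clusters. The late cluster had 49, 49 and 16 cells in MAKR5 root tip, MAKR5 whole root and PEAR1del. Relative to the early clusters, PEAR DOF genes had median log2 ratios of 0.94, 0.78 and 1.17 in the late cluster in that order. The cytokinin response regulator ARR4 was at 3.76, 2.75 and 5.84 in the 3 libraries. The PEAR1del value rests on 32 UMIs against 2, with a counting interval of 4.17 to 9.24. Sugar transport genes had medians of 1.18 in root tip (4 genes) and 1.16 in whole root (3 genes). Stress and wounding genes were at −2.57, 0.04 and 0.61.

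Median UMIs per cell of the late and early clusters were 26519 against 56263 in MAKR5 root tip, 14753 against 31139 in MAKR5 whole root and 13107 against 27693 in PEAR1del; the cause was not tested. The hypothesis that cell cycle genes stay on in the late cells was left open: the median log2 ratios of late over early were −1.21, −0.86 and −1.63, of which the highest, −0.86, did not fall under the bound of −1 set beforehand.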
